A study of Arabidopsis thaliana with 21 samples.

How the data were processed

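Messenger RNA was measured in 21 libraries of excised Arabidopsis leaves, 3 in each of 7 feeding groups. According to the submitters' processing notes, reads were aligned with Subread to TAIR10 and counted per gene with featureCounts, with no versions given, and libraries were made with a kit that does not keep the strand. The deposited table gives CPM, counts scaled to the library total, for 21156 gene loci in 21 columns, in the unit per the labels. Within every column 100.0% of the values were whole multiples of 1 read to a tolerance of 1e-06, which gave library totals of 19190821 to 27155547 reads assigned to genes (median 23657548). Values were absent in all 3 libraries of a group or in none of them: 2926 genes (13.8%) lacked values in at least 1 group and 18230 had values in all. No value was 0, so genes with no reads in some library of a group seem to have been left out of that group; such values were treated as absent. At most 6653 reads (0.0276%) of a library were not listed. The columns name the group but not which replicate of the labels they hold, so libraries are numbered by column.

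Groups were compared in R 4.3.3 with limma 3.58.1. A fit with 1 mean per group and an intensity-dependent prior variance was made to log2(CPM + 0.5) of all 21 libraries, for the 17794 genes with at least 1 CPM in at least 3 libraries; 354 of these lacked values in some group. Moderated tests were two-sided, p-values were adjusted by Benjamini-Hochberg over all genes of a comparison, and the threshold was 0.05. Of the 16 comparisons, 13 were chosen before the data were examined, together with most alternatives, the gene lists and the rule for naming genes. The other 3, PAP + ATP against PAP, PAP + LiCl against PAP and the interaction of ATP with LiCl in PAP-fed leaves, were added afterwards.

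The rule named, for each comparison of 2 groups, the 8 largest rises and 8 largest falls among genes past the threshold with a mean CPM of at least 5 and no overlap between the 3 and 3 libraries. For interactions it named 5 and 5 without the overlap condition. It further named the 4 members of each list with the smallest p in each planned comparison, and SAL1, XRN2, XRN3, XRN4, APX2, ELIP2, ZAT10 and DREB2A throughout. Pairs of neighbours were the 4 with the smallest p of the downstream gene in each comparison. The text prints those that carry a result and gives counts for the rest; genes listed in the part on other observations were chosen after their values were seen.

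A total of 20 lists of genes, 259 members, was written from general knowledge of Arabidopsis; 8 members whose symbol did not match the reference and 9 absent from the table were left out, which left 242. Lists were tested with limma's camera at a preset correlation of 0.01 between genes, and again with a correlation estimated per list, with Benjamini-Hochberg adjustment over the 20 lists; fry was run beside them. Counts of members past the threshold are given adjusted over all genes and adjusted over the list alone. Counts and medians cover the members tested in a comparison. Camera and fry used only those with values in all 7 groups, so some lists held fewer genes there.

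Gene positions came from TAIR10.1, which held 20952 (99.0%) of the loci. A gene was called downstream when the nearest gene upstream on its strand ended at most 500 bp before it and had at least 10 times its mean CPM, and convergent when the nearest gene past its own end lay on the opposite strand under the same limits. Of 17325 genes considered, 298 were downstream, 220 convergent and 562 isolated, with no gene within 2000 bp. The planned test compared the list's median change with 10000 random lists of isolated genes of the same expression deciles; an added test exchanged the labels of list and isolated genes within deciles, 10000 times, two-sided.

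The tests were tried on simulated data. Reads were simulated at the depth of the libraries, with genes drawn independently and the spread of each estimated from all 21 libraries. Of 200 genes changed between PAP and control, 82.4% of 2-fold and 29.2% of 4-fold changes were missed, with 5.35% false among the calls. Libraries within PAP and within control differed more than those of the other groups, so more may be missed in the data. In 100 simulations of the neighbour test without a shift, with genes drawn independently, the planned test gave p under 0.05 in 34% and the exchange in 8%. With a shift of 0.2 these were 88% and 67%. For this reason the text rests on the exchange, though the simulations do not show its error rate for correlated genes.

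Alternatives set beforehand were log2(CPM + 0.1), log2(CPM + 2), no filter, a mean CPM of at least 5, median-of-ratios scaling, a fit of only the compared groups, each library left out in turn, and edgeR 4.0.16 quasi-likelihood and DESeq2 1.42.0 on the recovered reads. For neighbours they were shorter and longer gaps, a ratio of 3 and scaling. Added alternatives were 1 surrogate variable (sva 3.50.0), leaving out libraries 4 and 20 together, array weights and, for neighbours, closely spaced genes in place of isolated ones. Principal components used the 17440 genes with values in all groups. Tables were made with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures with matplotlib 3.10.9. No column of the table was left out.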

Results

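Messenger RNA was sequenced from excised leaves of 35-day-old Arabidopsis thaliana plants, F1 hybrids of the Col-0 and Ler accessions, fed through the petiole. PAP is a phosphoadenosine phosphate that the lithium-sensitive phosphatase SAL1 breaks down and that inhibits the XRN exoribonucleases. The series title concerns RNA polymerase II running past gene ends into neighbouring genes in this pathway. Leaves received buffer alone (control), 1 mM ATP, 100 µM PAP, 100 mM LiCl, PAP + LiCl, PAP + ATP, or PAP + ATP + LiCl. Each of the 7 groups had 3 libraries, and no group received ATP with LiCl in the absence of PAP. The treatment notes give the PAP dose as 1 mM or 100 mM, so the 100 µM of the sample labels is open to doubt, and the feeding time is not given.

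The control libraries, numbered 1 to 3, held 20997704, 24622922 and 21655492 reads assigned to genes. The ATP libraries (4 to 6) held 23050737, 23623910 and 24471398, the PAP libraries (7 to 9) 25574560, 24073817 and 27155547, and the LiCl libraries (10 to 12) 23704375, 25416678 and 26590221. Those fed PAP + LiCl (13 to 15) held 21968070, 23551425 and 23944420, PAP + ATP (16 to 18) 22744596, 21945958 and 19190821, and PAP + ATP + LiCl (19 to 21) 23657548, 22219640 and 24438535. At this depth 1 read was worth between 0.0368 and 0.0521 CPM, reads scaled to the library total. Changes below are log2 ratios ± standard error with 3 libraries a group, and adjusted p is limma's after Benjamini-Hochberg correction. The p-values of genes and lists measure only the spread between these libraries, since the labels do not say whether they came from separate plants. Those of neighbouring genes exchange genes and hold the libraries fixed.

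LiCl separated the libraries more than any other treatment. All 9 libraries fed LiCl lay between 35.3 and 69.5 on the first principal component, which held 39.0% of the variance, and the other 12 lay between -81.6 and -14.5. Of 17440 genes with a value in every group, 6192 (35.5%) differed among the 7 groups in limma's F test. Libraries of the groups without LiCl differed more from each other: the median within-group SD of a gene was 0.40 in control, 0.37 in PAP, 0.31 in ATP and 0.32 in PAP + ATP. It was 0.25 in LiCl, 0.26 in PAP + LiCl and 0.26 in PAP + ATP + LiCl. The tests of genes pooled this spread over all 7 groups. Their p-values against control may therefore be too small, and those between groups fed LiCl too large.

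**Figure D1:**
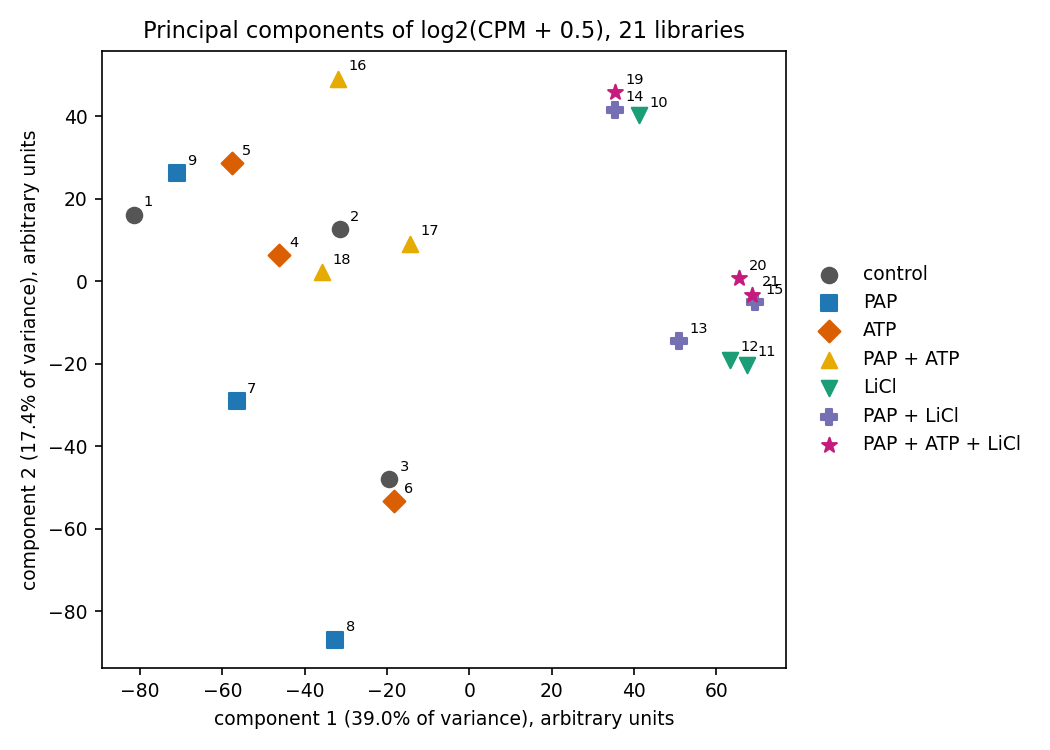
Each point is 1 of the 21 libraries, numbered, on the first (39.0% of variance) and second principal components of log2(CPM + 0.5), in arbitrary units. The 9 libraries fed LiCl lie at 35.3 or more on the first component and the other 12 at -14.5 or less.

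**Figure D2:**
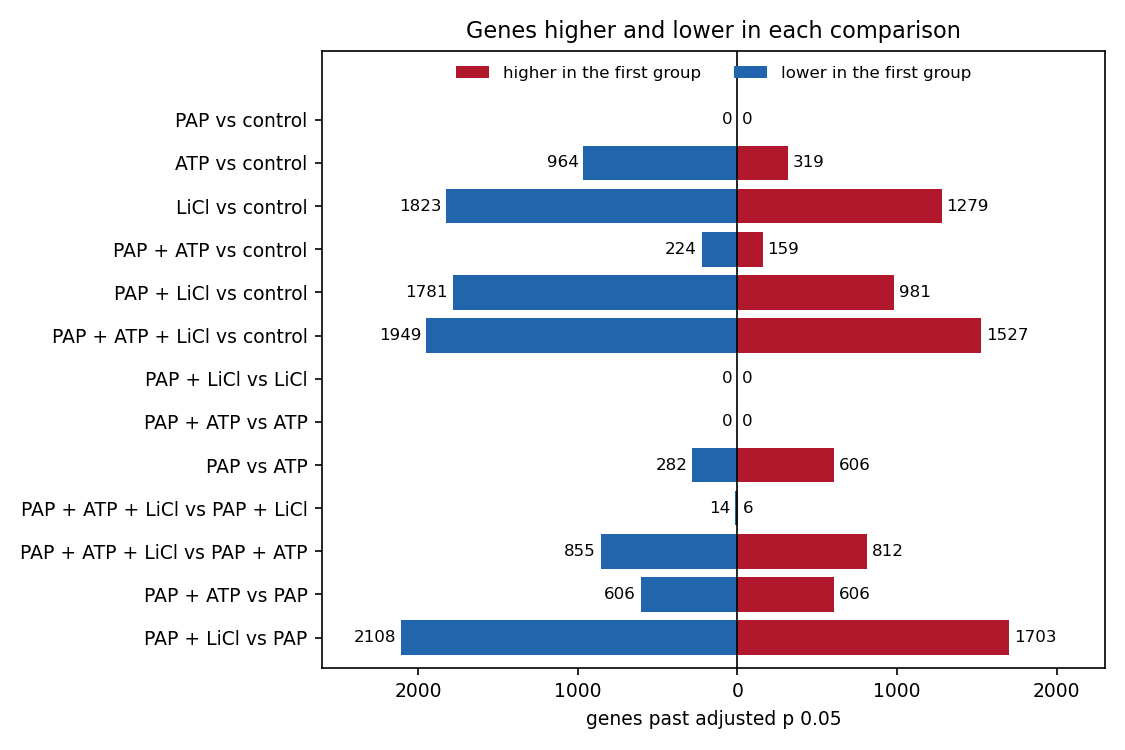
Bars give the number of genes past an adjusted p of 0.05 in each comparison of 2 groups, to the right for genes higher in the first group and to the left for genes lower. The largest bars are for PAP + LiCl against PAP (1703 higher and 2108 lower), and PAP against control, PAP + LiCl against LiCl and PAP + ATP against ATP have 0 genes.

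PAP against control asked what PAP did when its breakdown was not blocked. No gene passed the threshold. SAL1 stood at 177 ± 18.8 CPM (SD, n = 3) with PAP and 154 ± 59.0 in control; the changes of the exoribonuclease genes XRN2, XRN3 and XRN4 were -0.01 ± 0.38, -0.17 ± 0.34 and -0.03 ± 0.32, with adjusted p = 0.999, 0.997 and 0.999. ZAT10 and DREB2A, stress-responsive transcription factor genes, stood at 173 ± 138 and 8.83 ± 4.40 CPM with PAP and at 145 ± 89.1 and 8.08 ± 2.92 in control. APX2 and ELIP2, induced by high light, did not reach the expression filter and were not tested.

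With camera and its preset correlation, 4 of 20 fixed lists lay apart from other genes in the PAP leaves, although no member passed, adjusted over all genes or adjusted over the list alone. Photosynthesis genes (23, median change 0.22, adjusted p = 1.0e-04), abscisic acid and dehydration genes (25, 0.20, 0.036) and epidermis markers (4, 0.45, 0.0361) lay higher. Salicylic acid and immunity genes (14, -0.44, 0.0197) lay lower. With an estimated correlation the adjusted p values were 0.765, 0.765, 0.753 and 0.753. After median-of-ratios scaling the abscisic acid and epidermis lists no longer passed either. Without control library 2 no list passed. Among the 17657 genes tested by limma, 847 (4.80%) had an unadjusted p under 0.05 and the smallest adjusted p was 0.694. EdgeR called 0 genes and DESeq2 1, and limma called 4 without control library 1. The 95% confidence interval of a typical gene reached 0.65 to either side. In reads simulated at this depth with the spread of all 21 libraries, 82.4% of 2-fold and 29.2% of 4-fold changes were missed. Most 2-fold effects of PAP could thus have gone unseen, and smaller ones were not simulated.

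ATP against control asked what a nucleotide fed at 1 mM did. Genes of glucosinolate synthesis, sulfur-rich defence compounds of this plant family, fell: MYB29 (log2 -1.74 ± 0.37, adjusted p = 0.0121) and MYB28 (log2 -1.28 ± 0.35, adjusted p = 0.0374; not past after scaling), which encode transcription factors of aliphatic glucosinolate synthesis, and the synthesis enzyme gene CYP83A1 (log2 -1.75 ± 0.31, adjusted p = 0.00569). The largest rises included AT3G62950, a thioredoxin superfamily gene (log2 4.12 ± 0.48, adjusted p = 5.3e-04), AT5G61800, a pentatricopeptide repeat gene (3.56 ± 0.47), and PHI-1, a phosphate-responsive family gene (3.02 ± 0.60). The largest falls included TBL26 (log2 -3.39 ± 0.68, adjusted p = 0.00942) and the ferric reductase gene FRO8 (-2.81 ± 0.49). CYP707A3, which encodes an abscisic acid hydroxylase, rose (log2 2.55 ± 0.46, adjusted p = 0.006) while its relative CYP707A1 fell (-1.68 ± 0.42).

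Of 9 glucosinolate genes tested, 0 rose and 3 fell over all genes, and 7 fell adjusted over the list alone. Camera's adjusted p for the list was 4.6e-04, and adjusted p = 0.609 with an estimated correlation. Abscisic acid and dehydration genes lay higher (25 genes, median 0.78, adjusted p = 5.1e-06, and 0.609 with an estimated correlation), as did photosynthesis genes (23, 0.17, 0.00543, and 0.752 with an estimated correlation). The senescence (0.0224), epidermis (0.03) and high light (0.0337) lists also lay higher, each with an adjusted p of 0.609 with an estimated correlation, but not after scaling. These 6 were the only lists past camera, so the extracellular ATP and early damage list did not pass with ATP alone. Without control library 2 only 1 of the 20 lists passed. In the jasmonate list 0 of 20 genes rose and 2 fell, MYC2 (-1.19 ± 0.27) and CYP94C1 (-1.02 ± 0.27), and 3 fell adjusted over the list alone. Among 8 vascular markers the phloem sucrose carrier gene SUC2 rose (2.02-fold, log2 SE 0.24, adjusted p = 0.0212) and SWEET11 fell (-1.32 ± 0.39). In total 319 of 17667 genes rose and 964 fell. Median-of-ratios scaling moved the median change of all genes by 0.21 and gave 493 rises and 401 falls. With only these 2 groups in the fit limma called 15 genes, 11 up and 4 down, and edgeR in the full fit called 811. The total was 784 without control library 1, 530 without control library 2, 572 without ATP library 4 and 286 without ATP library 5. Library 4 had 1.22% of its reads from plastid genes and 0.996% from nuclear ribosomal RNA genes, and without it and library 20 together the total was 383.

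LiCl against control asked what LiCl, an inhibitor of SAL1, did on its own. No group received another salt, so blocked PAP breakdown and other effects of 100 mM LiCl cannot be told apart. Of 7 sulfur assimilation and starvation genes 4 fell: APR3, an adenylylsulfate reductase gene (log2 -2.44 ± 0.47, adjusted p = 0.00218), LSU2 (log2 -2.78 ± 0.68, adjusted p = 0.01), SDI1 (-2.59 ± 0.75) and the sulfate transporter gene SULTR1;2 (-1.33 ± 0.37). Of 7 flavonoid genes 3 fell: CHI (AT3G55120), encoding chalcone isomerase (log2 -2.05 ± 0.39, adjusted p = 0.00209), MYB75, a regulator of anthocyanin synthesis (-3.17 ± 0.88), and PAL1 (-1.87 ± 0.57). RBOHD, which encodes an NADPH oxidase of the plasma membrane, and WRKY33, a defence transcription factor gene, rose (2.46-fold, log2 SE 0.23, adjusted p = 0.0012, and log2 1.77 ± 0.45, adjusted p = 0.0122). CYP94B3, whose enzyme inactivates jasmonoyl-isoleucine, fell (log2 -3.27 ± 0.35, adjusted p = 1.7e-05), as did the jasmonate-responsive genes VSP1 (-3.47 ± 0.91) and AOC2 (-1.32 ± 0.32), while JAZ5 rose (1.15 ± 0.29).

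AHL (log2 -1.45 ± 0.34, adjusted p = 0.0071), which belongs to the same phosphatase family as SAL1, fell with LiCl. So did 3 genes whose enzymes make or use the sulfate donor PAPS: APK3 (-0.74 ± 0.22), SOT12 (-1.83 ± 0.55) and SOT16 (2.46-fold, log2 SE 0.27, adjusted p = 0.00356). SAL1 stood at 118 ± 4.93 CPM and XRN3 at 49.5 ± 4.12 CPM (SD, n = 3). Neither passed (log2 -0.31 ± 0.29, adjusted p = 0.488 for SAL1, and log2 0.93 ± 0.34, adjusted p = 0.0676 for XRN3). Among clock genes the morning gene CCA1 (2.83-fold, log2 SE 0.37, adjusted p = 0.0101) and RVE8 (0.94 ± 0.30) rose and the evening genes LUX (-1.58 ± 0.35), ELF4 (-1.28 ± 0.37) and ELF3 (-1.11 ± 0.35) fell. Ethylene synthesis genes ACS6 (2.01-fold, log2 SE 0.29, adjusted p = 0.0252), ACS8 (1.56 ± 0.51) and ACO4 (1.02 ± 0.33) rose and ACS2 fell (-1.54 ± 0.51). Of the largest changes, the uncharacterised gene AT2G32235 rose (log2 5.50 ± 0.73, adjusted p = 1.2e-04), as did the transporter gene ABCC6 (log2 4.91 ± 0.50, adjusted p = 1.2e-05; chromosome 3, 4202811 to 4208261 in TAIR10.1) and the early auxin gene IAA1 (3.69 ± 0.51). AT4G10290, a cupin superfamily gene (128-fold, log2 SE 0.46, adjusted p = 2.9e-07; chromosome 4, 6379701 to 6381829), the SAUR-like gene AT4G22620 (-4.62 ± 0.33) and GPT2, a glucose 6-phosphate carrier gene of plastids (-4.55 ± 0.86), fell.

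By list, 0 rose and 4 fell of 7 sulfur genes, 0 and 3 of 7 flavonoid genes, 1 and 5 of 21 jasmonate genes, 0 and 4 of 14 SAL1-PAP-XRN and PAPS genes, 2 and 0 of 10 extracellular ATP response genes, 2 and 3 of 13 clock genes and 3 and 1 of 12 ethylene genes. Adjusted over the list alone the counts were 0 and 4, 0 and 3, 2 and 6, 1 and 4, 4 and 0, 3 and 3, and 3 and 1. In the salicylic acid list EDS1 rose (1.26 ± 0.39) and WRKY70 fell (-2.64 ± 0.65). SUC2 (1.33 ± 0.24), RCA (1.19 ± 0.39), BAP1 (-2.06 ± 0.61), NHX1 (-1.62 ± 0.52), SAG101 (-1.22 ± 0.37) and CER6 (-1.52 ± 0.34) were the lone members that passed in 6 other lists. No list passed camera; the smallest adjusted p was 0.151, and 0.859 with an estimated correlation. By fry, which asks only whether a list moves one way, the flavonoid list had an adjusted p of 0.0322. In total 1279 of 17587 genes rose and 1823 fell, 865 and 1271 of them by more than 2-fold. After median-of-ratios scaling 1670 rose and 1683 fell. The total of 3102 became 1756 without control library 1, 1786 without LiCl library 11 and 1756 without LiCl library 12.

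**Figure D3:**
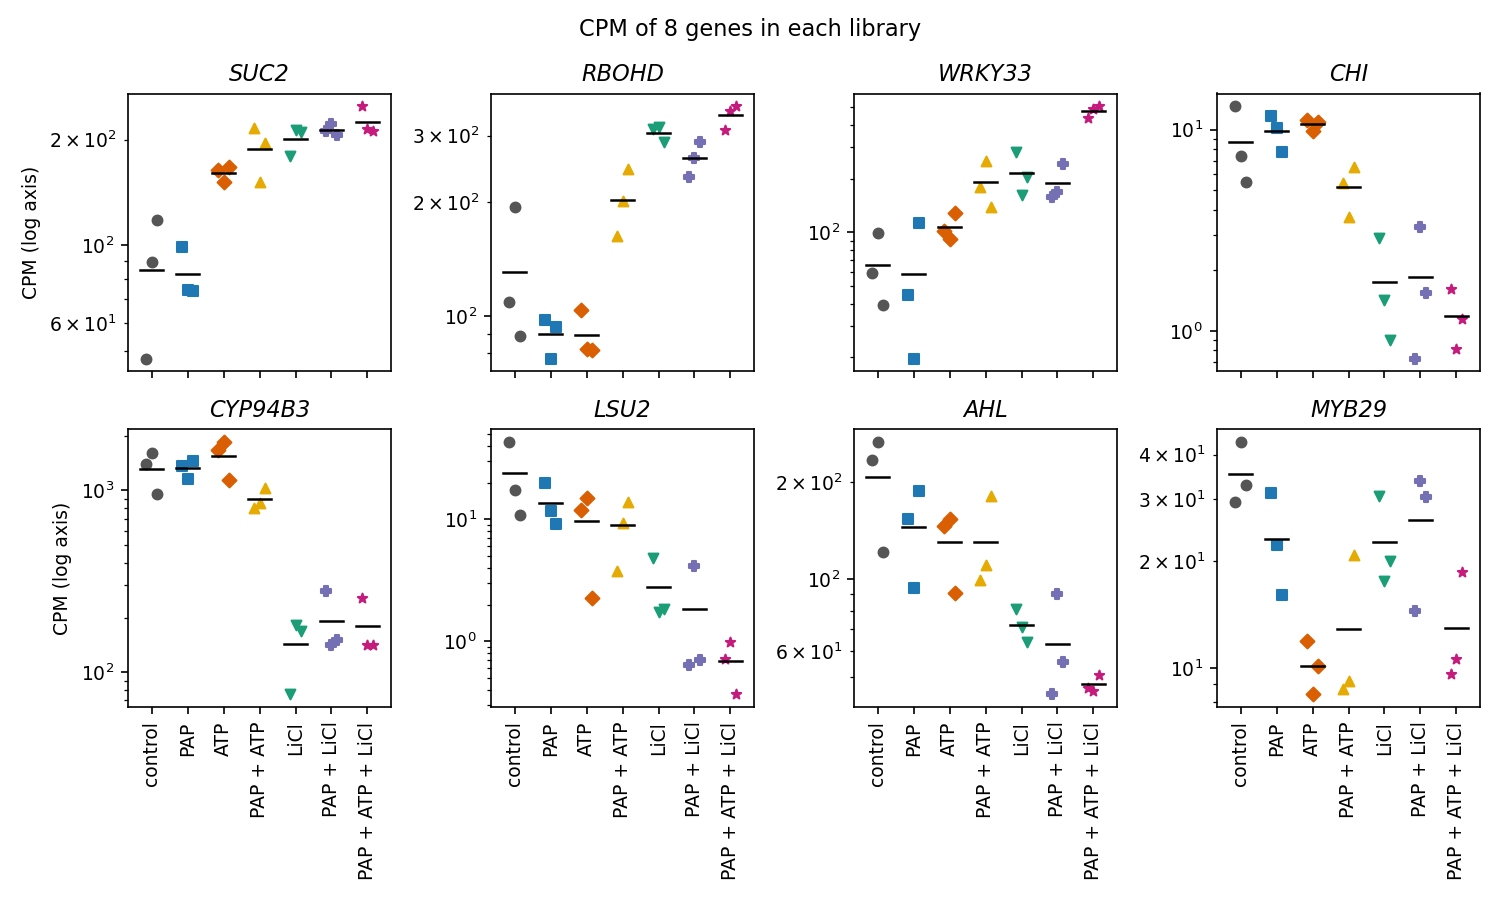
Points are CPM (log axis) of 8 genes in the 3 libraries of each group, and lines are group means. CYP94B3, CHI, LSU2 and AHL have lower means in the 3 groups fed LiCl than in control, RBOHD, WRKY33 and SUC2 higher ones, and MYB29 is lowest with ATP.

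PAP + LiCl gave PAP together with LiCl, an inhibitor of SAL1. Against control LSU2 (log2 -3.49 ± 0.68, adjusted p = 0.00249), APR3 (-2.66 ± 0.47), CHI (AT3G55120; -2.03 ± 0.39) and AHL (-1.69 ± 0.34) fell. RBOHD (1.07 ± 0.23), WRKY33 (1.59 ± 0.45), MPK3 (0.83 ± 0.27) and MPK11 (2.12 ± 0.58), the last 2 of them kinase genes of defence signalling, rose. Of 13 salicylic acid genes 3 rose, ICS1 (log2 1.13 ± 0.34, adjusted p = 0.0306), EDS1 (1.45 ± 0.39) and CBP60G (1.44 ± 0.44), and 0 fell, or 3 and 1 adjusted over the list alone. The list as a whole did not pass camera (median 0.01, adjusted p = 0.693, and 0.957 with an estimated correlation). The largest rises were AT2G32235 (log2 6.18 ± 0.73, adjusted p = 4.6e-05) and ABCC6 (log2 5.87 ± 0.50, adjusted p = 2.4e-06), and the largest fall was AT4G10290 (log2 -6.59 ± 0.46, adjusted p = 6.4e-07). The extracellular ATP list (4 of 10 up, 5 adjusted over the list alone) and photosynthesis list (0 of 23 up, median 0.40) lay higher by camera, each at an adjusted p of 0.011. The sulfur list (3 of 7 down, 5 adjusted over the list alone) lay lower (0.0193). For each of the 3, adjusted p = 0.957 with an estimated correlation. In total 981 of 17602 genes rose and 1781 fell, or 2762. This became 1538 without control library 1 and 1276 without PAP + LiCl library 15. Scaling moved the median of all genes by 0.11 and gave 1439 rises and 1433 falls.

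PAP + LiCl against LiCl asked what PAP added in leaves also fed LiCl. Only RNA was measured here, so whether LiCl blocked the breakdown of PAP is not known. No gene passed by limma among 17609: 130 (0.738%) had an unadjusted p under 0.05, the smallest adjusted p was 0.793, and edgeR and DESeq2 also called 0. Salicylic acid and immunity genes lay higher with PAP (14 genes, median 0.50, camera adjusted p = 4.5e-08, and 0.117 with an estimated correlation). Photosynthesis (median 0.15, 0.00115, and 0.737 with an estimated correlation) and high light genes (0.18, 0.021, and 0.551) did so too, the last not after scaling. Among these lists 0 members passed, adjusted over all genes or adjusted over the list alone. The interaction of PAP with LiCl called 0 of 17505 genes by limma, 0 by edgeR and 4 by DESeq2, with 318 genes at an unadjusted p under 0.05.

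The effect of LiCl was compared between leaves without and with PAP. PAP + LiCl against PAP, added after the data were seen, gave 1703 rises and 2108 falls among 17603 genes. Over 17505 genes tested in both, 930 rose in both this comparison and LiCl against control (124 would if the calls were independent), 1315 fell in both (217) and 0 went in opposite directions. Fold changes of these comparisons, which share no library, correlated across genes at r = 0.86, with genes not being independent replicates. The 2393 genes called without PAP + LiCl library 15 were the fewest of any left-out library.

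PAP + ATP against control asked what the 2 nucleotides did together. The largest rises were AT5G61800 (log2 3.33 ± 0.47, adjusted p = 0.00461), AT5G46500 (3.14 ± 0.38), the phloem protein gene PP2-B13 (3.12 ± 0.64) and PHI-1 (3.06 ± 0.60), and the largest falls were AT1G30280, a DnaJ-domain gene (log2 -2.61 ± 0.49, adjusted p = 0.0153), and SAUR9 (-2.59 ± 0.53). MYB29 (-1.51 ± 0.37), CYP83A1 (-1.35 ± 0.31) and PR5 (-1.73 ± 0.44) fell, and SUC2 rose (1.22 ± 0.24). Clock genes lay higher (13 genes, median 0.56, camera adjusted p = 3.0e-04, and 0.176 with an estimated correlation), as did extracellular ATP response genes (10, 0.71, 0.00261, and 0.93 with an estimated correlation). Heat shock genes (7, 1.11, 0.00883, and 0.884 with an estimated correlation) and abscisic acid genes (25, 0.33, 0.0233, and 0.93) lay higher too, the latter not after scaling. No member of these 4 lists passed over all genes, and adjusted over the list alone 3 clock genes and 5 extracellular ATP response genes rose.

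In total 159 of 17674 genes rose and 224 fell with PAP + ATP against control; scaling moved the median of all genes by 0.10 and gave 310 and 176. The total of 383 depended on single libraries: it was 38 without control library 1, 62 without PAP + ATP library 16, 61 without library 17 and 1260 without library 18, and limma called 0 when only these 2 groups entered the fit.

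PAP + ATP against ATP asked whether PAP altered the response to ATP. No gene passed by limma among 17710, while 1897 had an unadjusted p under 0.05; the smallest adjusted p was 0.103, edgeR called 0 genes and DESeq2 127. Glucosinolate genes (9, median 0.67, camera adjusted p = 0.0043) and jasmonate genes (19, 0.63, 0.00626) lay higher with PAP, and 4 and 6 of them rose adjusted over the list alone. Extracellular ATP (0.79, 0.0253), clock (0.44, 0.0098) and unfolded protein genes (0.57, 0.0115) lay higher as well. Photosynthesis (-0.28, 6.1e-04), abscisic acid (-0.44, 0.0043), high light (-0.26, 0.0138) and epidermis genes (-0.58, 0.018) lay lower. For all 9 lists the adjusted p was 0.474 with an estimated correlation; scaling moved the median of all genes by -0.11.

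The interaction of PAP with ATP called 0 of 17605 genes by limma, 0 by edgeR and 160 by DESeq2, with 2189 genes at an unadjusted p under 0.05; without control library 1 limma called 310. PAP + ATP against PAP, added after the data were seen, gave 606 rises and 606 falls among 17673 genes. Of 17605 genes in both, 95 rose and 139 fell both here and with ATP against control (10.8 and 33.1 if independent), and 1 went in opposite directions. The fold changes correlated across genes at r = 0.40. Agreement was not confined to ATP. LiCl against control, which shares no library with PAP + ATP against PAP either, gave r = 0.34 with it. Here 185 genes were up and 191 down in both (43.5 and 62.8 if independent) and 30 went in opposite directions. ATP against control and PAP + LiCl against PAP agreed less (r = 0.13). In that pair 51 genes were up and 202 down in both (30.2 and 115 if independent), and 152 went in opposite directions. The total of 1212 was 98 without PAP + ATP library 16, 189 without library 17, 263 without PAP library 7, 212 without PAP library 8 and 2028 without PAP + ATP library 18.

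PAP against ATP compared 2 adenine nucleotides at different doses, 100 µM and 1 mM by the sample labels, so the difference in structure was not tested at a matched dose. BT2, a BTB and TAZ domain gene, was lower with PAP (log2 -3.61 ± 0.41, adjusted p = 0.00104), as were HOS15, a WD-40 repeat gene (log2 -2.76 ± 0.32, adjusted p = 0.00104), PHI-1 (-3.36 ± 0.60), PP2-B13 (-3.66 ± 0.64) and the glutathione transferase gene GSTU11 (-3.25 ± 0.63). TBL26 (log2 3.78 ± 0.68, adjusted p = 0.00911), the protease inhibitor gene AT1G73325 (3.08 ± 0.66) and CYP83A1 (1.22 ± 0.31) were higher with PAP. ASN1, a dark-inducible asparagine synthetase gene, was lower with PAP (-2.17 ± 0.58), and so was SUC2 (-0.97 ± 0.24). Of 17666 genes, 606 were higher and 282 lower with PAP, and scaling, which moved the median of all genes by -0.14, gave 493 and 497. The total of 888 was 241 without ATP library 4, 56 without ATP library 5, 307 without PAP library 7, 171 without PAP library 8 and 427 without PAP library 9, and 123 without libraries 4 and 20.

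PAP + ATP + LiCl against control asked what the 3 compounds did together. Genes of the extracellular ATP and early damage list rose: WRKY33 (log2 2.95 ± 0.45, adjusted p = 3.0e-04), CYP81F2, an indole glucosinolate hydroxylase gene (log2 3.33 ± 0.73, adjusted p = 0.00443), MPK3 (1.54 ± 0.27), RBOHD (1.45 ± 0.23) and MPK11 (2.58 ± 0.58). Without ATP, WRKY33 and RBOHD also rose with LiCl, and MPK3 and MPK11 with PAP + LiCl. The list did not pass camera with ATP alone but did with PAP + ATP at the preset correlation. It was not tested in PAP + ATP + LiCl against PAP + LiCl, so the rises of its members here cannot be assigned to ATP. Sulfur genes LSU2 (log2 -4.16 ± 0.68, adjusted p = 5.5e-04), APR3 (-2.25 ± 0.47), SDI1 (-2.79 ± 0.75) and APR1 (2.83-fold, log2 SE 0.51, adjusted p = 0.0461) fell. So did the flavonoid genes CHI (AT3G55120; -2.38 ± 0.39), MYB75 (-3.57 ± 0.88), PAL1 (-1.94 ± 0.57) and FLS1 (-1.71 ± 0.51). TPS03, a terpene synthase gene (log2 -5.77 ± 0.73, adjusted p = 6.4e-05), and BSMT1, encoding a methyltransferase of salicylic and benzoic acid (log2 -5.22 ± 0.88, adjusted p = 6.8e-04), were among the largest falls, after AT4G10290 (log2 -7.04 ± 0.46, adjusted p = 2.7e-07). Abscisic acid-responsive RD20 (-1.65 ± 0.48) and RD26 (-1.55 ± 0.46) and the phosphatase gene HAI1 (-2.83 ± 0.85) fell, CYP707A3 rose (1.72 ± 0.46), and AHL fell (log2 -2.04 ± 0.34, adjusted p = 5.6e-04).

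The extracellular ATP list (5 of 10 up, 6 adjusted over the list alone) lay higher by camera (adjusted p = 6.0e-04, and 0.918 with an estimated correlation). The sulfur list (4 of 6 down, 5 adjusted over the list alone; 0.0206, and 0.918 with an estimated correlation) and the flavonoid list (4 of 7 down, 5 adjusted over the list alone; 0.0452, and 0.8 with an estimated correlation) lay lower. By fry, 4 of the 20 lists passed. In the mitochondrial dysfunction list 1 of 6 genes fell, NAC013 (-1.18 ± 0.36), and of 6 guard cell markers 0 passed here or in any other comparison with control. The plastid gene ATCG00030 was also among the 8 largest rises (3.93 ± 0.73). Library 20 had 0.475% of its reads from plastid genes and 0.327% from nuclear ribosomal RNA genes. In total 1527 of 17621 genes rose and 1949 fell, and scaling gave 1914 and 1800. The total of 3476 became 1785 without control library 1, and 1984 without library 20. Without libraries 4 and 20 it was 1757, with 2 libraries left in the group.

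PAP + ATP + LiCl against PAP + LiCl asked what ATP added to the other compounds. The CBL-interacting kinase gene CIPK20 (log2 1.89 ± 0.33, adjusted p = 0.0248) and AAE5, an acyl activating enzyme gene (log2 1.69 ± 0.28, adjusted p = 0.0193), rose, and ABCC6 (log2 -3.22 ± 0.50, adjusted p = 0.0129) and AT1G76170 (log2 -1.65 ± 0.23, adjusted p = 0.00984) fell. Of 17638 genes, 6 rose and 14 fell, and 1268 had an unadjusted p under 0.05. The count rested on a few libraries: it was 0 without library 20, 4 without library 14, 7 without library 15 and 4 without library 19, and 0 when only these 2 groups entered the fit.

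PAP + ATP + LiCl against PAP + ATP asked what LiCl added to the nucleotides. AT4G10290 (log2 -5.93 ± 0.46, adjusted p = 4.2e-06), TPS03 (-4.87 ± 0.73), CYP94B3 (log2 -2.37 ± 0.35, adjusted p = 5.7e-04), SDI1 (-3.30 ± 0.75) and LSU2 (-2.86 ± 0.68) fell. IAA1 (log2 3.47 ± 0.51, adjusted p = 5.6e-04), MAKR6 (3.67 ± 0.47) and the transcription factor gene WRKY53 (3.14 ± 0.73) rose, and the abscisic acid-responsive genes RD26 (-1.90 ± 0.46), RD22 (-1.28 ± 0.32) and RD20 (-1.77 ± 0.48) fell. Of 17661 genes, 812 rose and 855 fell. Among 17519 genes also tested in LiCl against control, a comparison with no library in common, 477 rose in both (58.6 if independent), 587 fell in both (85.8), 1 went in opposite directions, and r across genes was 0.73. The total of 1667 was 1042 without PAP + ATP library 16, 721 without library 20, 826 without library 21 and 634 without libraries 4 and 20.

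Neighbouring genes were compared because the series title names transcription that runs past gene ends. In 6 comparisons, genes that lay within 500 bp downstream of a gene on the same strand with at least 10 times their expression had higher fold changes than isolated genes of like expression, and PAP + LiCl against LiCl was a 7th. By camera with an estimated correlation between genes the list passed in none of them (p from 0.0915 to 0.741). With PAP + LiCl against control the median change of the 298 downstream genes was 0.19 and that of isolated genes -0.20. These medians were 0.12 and -0.20 with LiCl and 0.04 and -0.05 with PAP. They were 0.03 and -0.32 with ATP, 0.04 and -0.27 with PAP + ATP and 0.05 and -0.18 with PAP + ATP + LiCl. Before scaling, the difference in these groups and in LiCl lay mostly in lower isolated genes. This division depended on the scaling, which moved both medians, to 0.18 and -0.15 with ATP and to 0.26 and -0.12 with PAP + LiCl. Of the downstream genes 46 rose and 9 fell with PAP + LiCl. The counts were 30 and 6 with ATP, 34 and 13 with LiCl, 13 and 2 with PAP + ATP and 20 and 17 with PAP + ATP + LiCl. In PAP + LiCl, NRPD7, an RNA polymerase IV and V subunit gene at chromosome 3, 8115065 to 8116253, rose by 2.99 ± 0.38 (adjusted p = 9.3e-05). APS1, an ATP sulfurylase gene ending 40 bp upstream, stood at 0.59 ± 0.25 (adjusted p = 0.131). AT2G32235 (chromosome 2, 13682557 to 13684248) begins 50 bp past the end of AT2G32240 and rose by 5.50 ± 0.73 with LiCl, while AT2G32240 rose by 2.49 ± 0.72 (adjusted p = 0.025). With ATP, AT1G72125 rose by 2.54 ± 0.37 (adjusted p = 0.00196) 6 bp past AT1G72120, which stood at 0.02 ± 0.45, and AT3G21660 rose by 3.95 ± 0.62 downstream of AT3G21670 (-0.65 ± 0.39). Not every member rose, and some of the pairs with the smallest p fell. AT5G16200 fell with LiCl (-2.83 ± 0.28), PAP + LiCl (-2.56 ± 0.28) and PAP + ATP + LiCl (-2.75 ± 0.28). AT3G23605 fell with LiCl (-1.92 ± 0.24), AT1G20030 with PAP + ATP + LiCl (-3.46 ± 0.42) and AT2G39445 with PAP + ATP (-0.91 ± 0.18).

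**Figure D4:**
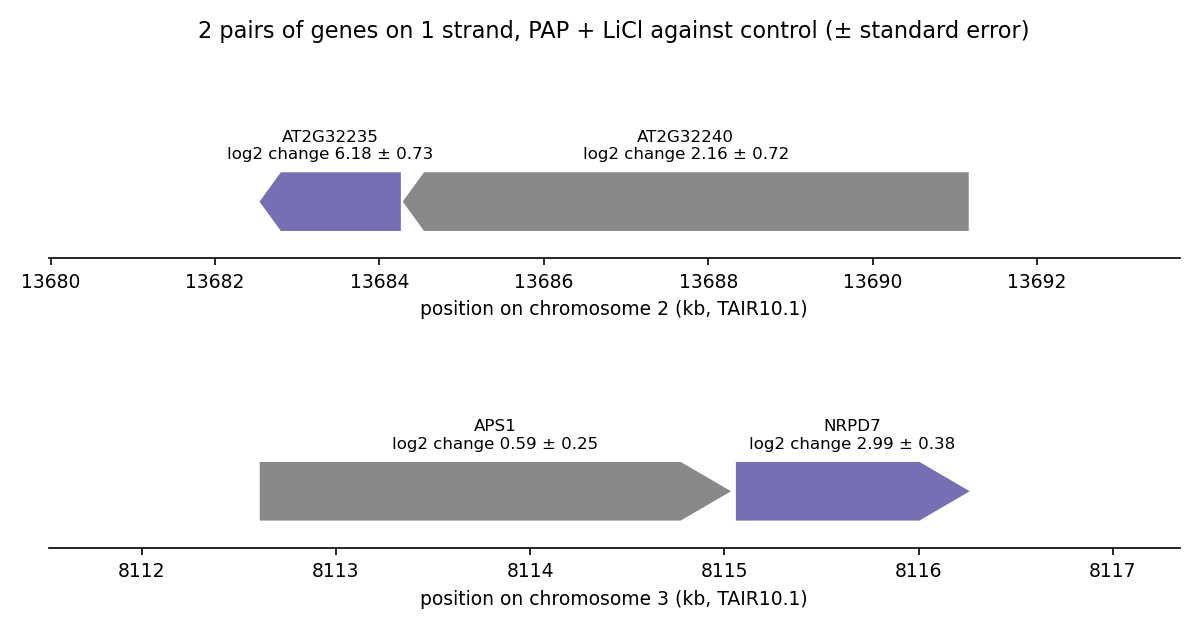
Arrows show 2 pairs of genes to scale on TAIR10.1, pointing in the direction of transcription, with the log2 change in PAP + LiCl against control ± standard error. AT2G32235 and NRPD7 lie 50 and 40 bp past the ends of AT2G32240 and APS1. AT1G76170, which rose (2.18 ± 0.23), and AT5G16200, which fell (-2.56 ± 0.28), had smaller p in this comparison and are not drawn.

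The planned test gave p under 0.05 in 34% of simulations without a shift, so a test that exchanges list membership between downstream and isolated genes within expression deciles (8%) was added after the data were seen. Those simulations drew genes independently, whereas camera estimated a correlation of 0.15 within the downstream list, so the permutation p values may be too small. By this exchange the list differed by 0.30 in PAP + LiCl and 0.26 in ATP (each permutation p = 0.0001, the smallest possible, two-sided). PAP + ATP gave 0.18 (0.0001), LiCl 0.19 (0.002), PAP + ATP + LiCl 0.17 (0.0065) and PAP 0.07 (0.0019), and these 6 comparisons share the control libraries. PAP + LiCl against LiCl gave 0.10 (0.0001), with no downstream gene past the threshold, and PAP + ATP against ATP -0.01 (0.641). Between single libraries the same difference overlapped, running from -0.09 to 0.28 in LiCl and from -0.11 to 0.34 in PAP + LiCl. Among 220 genes that face a strongly expressed gene on the opposite strand, the exchange gave permutation p values from 0.341 to 0.915. By camera the downstream list passed at a preset correlation in 6 of the 8 comparisons and in 0 with an estimated correlation (p = 0.449 for PAP, 0.242 for ATP, 0.544 for LiCl, 0.358 for PAP + ATP, 0.259 for PAP + LiCl, 0.741 for PAP + ATP + LiCl, 0.0915 for PAP + LiCl against LiCl and 0.641 for PAP + ATP against ATP). The exchange was no longer past 0.05 in PAP without PAP library 9 (0.02, permutation p = 0.373) or control library 1 (0.06), in PAP + LiCl against LiCl without library 14 (0.02, p = 0.305) and in PAP + ATP + LiCl without library 21 (0.11, p = 0.0518).

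**Figure D5:**
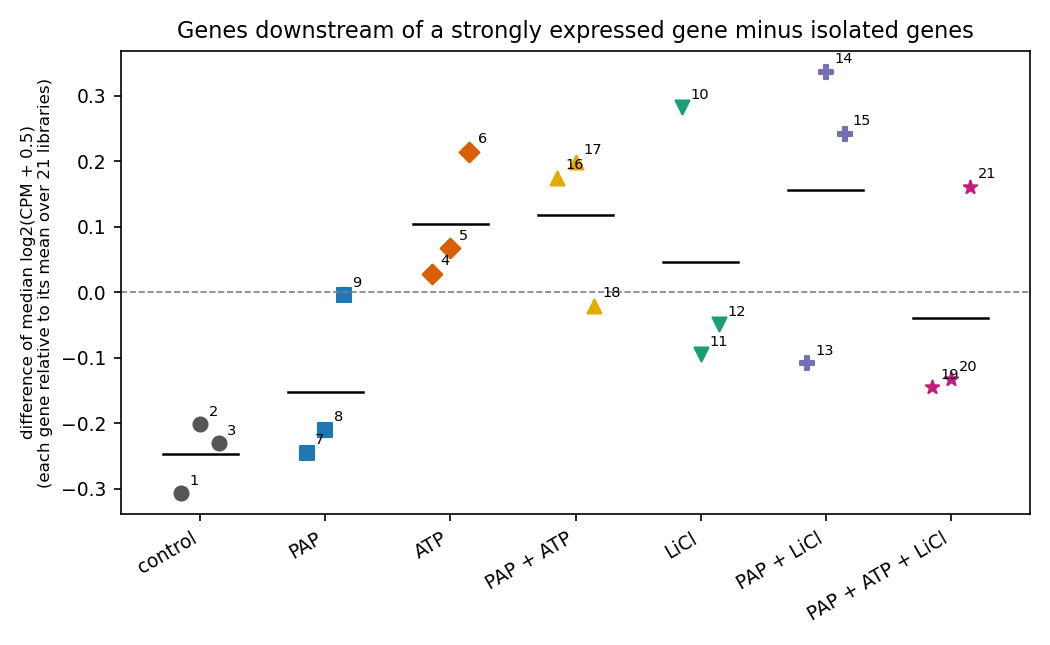
Points are the 21 libraries, numbered, and the vertical axis is the median of 298 downstream genes minus that of 562 isolated genes, in log2(CPM + 0.5) relative to each gene's mean over all libraries; lines are group means. Control libraries lie between -0.31 and -0.20, ATP libraries between 0.03 and 0.21, and PAP + LiCl libraries between -0.11 and 0.34.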

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

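The question whether ATP acted differently with LiCl among PAP-fed leaves and every test of it were chosen only after the data were seen, though the bound for its splits was set before they were counted. By limma's test of that difference, 5 of 17541 genes passed, and 1518 had an unadjusted p under 0.05. For ABCC6, a multidrug resistance-associated transporter gene, the effect of ATP was lower with LiCl by a log2 difference of -4.83 ± 0.70 (adjusted p = 0.0206, n = 3 a group). Its mean stood at 55.3 CPM in PAP + LiCl and 6.48 in PAP + ATP + LiCl, against 1.22 in PAP and 5.18 in PAP + ATP. AT5G60310, a lectin kinase gene, differed by -4.13 ± 0.54 (adjusted p = 0.00862), AT5G61800 by -4.27 ± 0.67 (0.0368) and AT1G51770, a glycosyltransferase family gene, by -4.30 ± 0.72 (0.0499). AT3G53730, a histone gene, differed the other way, by 1.97 ± 0.33 (0.0499), with means of 46.9 CPM in PAP, 16.1 in PAP + ATP, 6.78 in PAP + LiCl and 9.57 in PAP + ATP + LiCl.

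Chance is not excluded for this number: 9 of 100 splits of the 12 libraries, the real one included, gave 5 or more genes, and the highest other gave 1195. These splits mix libraries with and without LiCl, so their counts can hold the effect of LiCl itself. The count was 0 without PAP + ATP library 17, 1 without library 14, 15, 19 or 20, 2 without PAP library 8, 3 without PAP library 7, 8 without library 21, 10 without library 13 and 25 without library 18. By edgeR it was 18 and by DESeq2 121, and without libraries 4 and 20 it was 0.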

How the results depend on the processing

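The surrogate variable, the fit without libraries 4 and 20, the comparisons of PAP + ATP and PAP + LiCl with PAP, the interaction of ATP with LiCl, the label exchange, the comparison of downstream with closely spaced genes, camera with an estimated correlation for neighbours, and leaving out libraries for lists and neighbours were tests chosen only after the data were seen. No paired analysis was possible because the columns carry no replicate numbers, so the planned replicate block was not run for genes or lists. Array weights were tried, but their estimate did not converge and no value is given. Where 1 library was left out of 3, the fit pooled the spread over all groups.

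With only the compared groups in the fit the counts were 15 for ATP against control, 1162 for LiCl, 0 for PAP + ATP, 1054 for PAP + LiCl, 1747 for PAP + ATP + LiCl, 1 for PAP against ATP, 0 for PAP + ATP + LiCl against PAP + LiCl, 8 for PAP + ATP against PAP and 1 for the interaction of ATP with LiCl. With 1 surrogate variable they were 9641 for any difference among groups, 2774 for ATP, 1763 for PAP + ATP, 4281 for PAP + LiCl, 2473 for PAP against ATP, 62 for PAP + ATP + LiCl against PAP + LiCl and 2508 against PAP + ATP, 3081 for PAP + ATP against PAP, 5915 for PAP + LiCl against PAP and 27 for the interaction of ATP with LiCl. DESeq2 gave 1 for PAP, 1112 for PAP + ATP, 127 for PAP + ATP against ATP, 2017 for PAP against ATP, 136 for PAP + ATP + LiCl against PAP + LiCl and 2587 against PAP + ATP, 4 for PAP with LiCl, 160 for PAP with ATP, 2536 for PAP + ATP against PAP and 121 for ATP with LiCl. EdgeR gave 811 for ATP and 18 for the interaction of ATP with LiCl.

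A mean CPM of at least 5 gave 845 for ATP, 245 for PAP + ATP, 531 for PAP against ATP, 3 for PAP + ATP + LiCl against PAP + LiCl, 1 for the interaction of PAP with ATP and 3 for that of ATP with LiCl. That last count was 2 with log2(CPM + 0.1), 13 with log2(CPM + 2), 10 with no filter and 21 with scaling. Without libraries 4 and 20 the counts were 383 for ATP, 110 for PAP + ATP, 1757 for PAP + ATP + LiCl, 123 for PAP against ATP, 0 for PAP + ATP + LiCl against PAP + LiCl and 634 against PAP + ATP, 492 for PAP + ATP against PAP and 0 for ATP with LiCl.

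With each library left out in turn, counts ran from 5174 (without library 20) to 6556 (without library 18) for any difference among groups, 0 to 4 for PAP, 286 to 1266 for ATP, 1756 to 3605 for LiCl, 38 to 1260 for PAP + ATP, 1276 to 3023 for PAP + LiCl and 1785 to 3830 for PAP + ATP + LiCl. The highest were reached without control library 3 for ATP, LiCl, PAP + LiCl and PAP + ATP + LiCl. They ran from 0 to 3 for PAP + ATP against ATP (3 without library 16), 56 to 1181 (without ATP library 6) for PAP against ATP, 0 to 16 (without library 21) for PAP + ATP + LiCl against PAP + LiCl and 721 to 1535 (without library 19) against PAP + ATP. For PAP + ATP against PAP they ran from 98 to 2028, for PAP + LiCl against PAP from 2393 to 3251 (without PAP library 8), for the interaction of PAP with ATP from 0 to 310 (310 without control library 1, 3 without PAP library 9) and for ATP with LiCl from 0 to 25.

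Of 20 gene lists, camera with an estimated correlation passed 0 in every comparison, against 4 for PAP, 6 for ATP, 4 for PAP + ATP, 3 for PAP + LiCl, 3 for PAP + ATP + LiCl, 3 for PAP + LiCl against LiCl and 9 for PAP + ATP against ATP at the preset one. Scaling left 2 for PAP and 3 for ATP. With libraries left out, lists past ran from 0 (without control library 2; 2 without PAP library 8) to 6 for PAP, 1 (without control library 2) to 7 for ATP, and 0 to 2 for LiCl (2 without control library 2; 1 without control library 3, LiCl library 10 or 11). They ran from 2 (without control library 2) to 4 for PAP + ATP and 1 (without library 13) to 4 for PAP + LiCl. For PAP + ATP + LiCl they ran from 1 (without control library 1) to 5 (without control library 3 or library 19), and for PAP + LiCl against LiCl from 2 to 7 (without library 11 or 14). Fry, which asks only whether a list moves one way, passed 1 list each for ATP, LiCl, PAP + ATP and PAP + LiCl. It passed 4 for PAP + ATP + LiCl and 0 for PAP, PAP + LiCl against LiCl and PAP + ATP against ATP.

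Neighbour differences against random lists, the planned test, ran with 1 library left out for downstream genes from 0.0519 (without PAP library 9, no longer past 0.05) to 0.139 for PAP, and 0.00794 (without library 14, no longer past 0.05) to 0.274 for PAP + LiCl against LiCl. For PAP + ATP against ATP they ran from -0.115 (without ATP library 5) to 0.0512 (without ATP library 6), both past 0.05. Convergent genes in the same test ran from -0.0640 (without control library 1, past 0.05) to 0.0653 for PAP (0.0574 without control library 2, past 0.05), -0.0178 to 0.171 (without ATP library 5, past 0.05; 0.117 without control library 2, past 0.05) for ATP, 0.00457 to 0.118 (without control library 2, past 0.05) for PAP + ATP and 0.0208 to 0.115 (without library 19, past 0.05) for PAP + ATP + LiCl. They ran from -0.0366 (without LiCl library 11) to 0.0993 (without library 13) for PAP + LiCl against LiCl, both past 0.05 (as was 0.0668 without LiCl library 10), and 0.0145 to 0.0625 (without library 16, past 0.05) for PAP + ATP against ATP. A ratio of at least 3 gave convergent genes 0.0513 for PAP against random lists, past 0.05, but 0.0268 by label exchange (permutation p = 0.163).

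By label exchange downstream genes ran from 0.0242 to 0.1002 for PAP, 0.111 to 0.206 for PAP + ATP + LiCl and 0.0225 to 0.197 for PAP + LiCl against LiCl. Convergent genes ran by exchange from -0.0432 to 0.0753 (without control library 3, permutation p = 0.0301) for PAP, and in the other comparisons the exchange called them with 0 of the libraries left out. With an estimated correlation camera gave the downstream list p = 0.449 for PAP, 0.242 for ATP, 0.544 for LiCl, 0.358 for PAP + ATP, 0.259 for PAP + LiCl and 0.0915 for PAP + LiCl against LiCl.

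Among 1227 results for single named genes, 263 were past the threshold. Over 20446 alternative values for them, 792 lost a call, 298 gained one and 0 reversed a called direction. Only the compared groups in the fit lost 129 and gained 6, DESeq2 lost 4 and gained 72, scaling lost 21 and gained 13, and the surrogate variable lost 0 and gained 101. Leaving out a library lost 489 and gained 87 of 8394. Whichever library was left out, 13 of 27 called named genes kept their call for ATP against control, 29 of 49 for LiCl, 2 of 20 for PAP + ATP, 23 of 43 for PAP + LiCl and 32 of 56 for PAP + ATP + LiCl. The same held for 4 of 21 in PAP against ATP, 0 of 9 in PAP + ATP + LiCl against PAP + LiCl and 18 of 38 against PAP + ATP.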

Other observations

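Tests chosen only after the result was seen were the process terms, the trade of a control with a PAP library, the comparison of downstream with convergent genes, the label exchange, the senescence list along the shared axis, and the splits of the added comparisons.

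Genes annotated to nucleosome assembly, which include the histone genes, were among those that fell. Of 47 such genes 31 fell and 0 rose with LiCl against control (median change -1.41, camera adjusted p over 131 terms 3.5e-16), 31 fell and 1 rose with PAP + LiCl (-1.20) and 27 fell and 0 rose with PAP + ATP + LiCl (-1.08). With PAP + ATP 15 fell (-0.74) and with ATP 9 fell (-0.48); differences between treatments were not tested. With an estimated correlation the adjusted p values were 0.983 or more for each of these.

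A part of the genes annotated to translation and ribosome biogenesis fell. Of 330 translation genes 71 fell and 2 rose with PAP + ATP + LiCl (median -0.52, adjusted p = 2.7e-09) and 8 fell with PAP + ATP (-0.50, 4.5e-14). Of 89 ribosome biogenesis genes 22 fell and 0 rose (-0.59, 6.7e-09) and 5 fell and 0 rose (-0.56, 4.9e-13) in the same comparisons, and 8 fell with PAP + LiCl (-0.35, 0.0264). Genes annotated to the innate immune response lay higher, with 17 of 48 up and 1 down for PAP + ATP + LiCl (median 0.75, adjusted p = 3.1e-05) and 6 up for PAP + ATP (0.72, 2.1e-09). With an estimated correlation the adjusted p was 0.987 for PAP + ATP + LiCl, 0.998 for PAP + ATP and 0.984 for PAP + LiCl in all of these.

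PAP against control called 0 genes by limma and edgeR and 1 by DESeq2, with 847 at an unadjusted p under 0.05. A shared axis within groups that hides an effect of PAP was tested with 1 surrogate variable, which still gave 0 genes, and the explanation of 1 odd library among the 6 was tested by leaving each out, which gave at most 4 (without control library 1). A control and a PAP library exchanged may be a candidate explanation: control library 3 traded with PAP library 9 gave 1623 genes, control library 1 with PAP library 8 gave 1172, and the other 7 trades gave 0. The changes after the first trade correlated at r = 0.68, and after the second at r = -0.66, with the axis along which libraries of the other 15 vary within groups (r = 0.33 for the labels as given). An exchange and a spread of leaves along that axis therefore cannot be told apart. PAP removed by SAL1, a biological explanation, stays open. The changes with PAP against control did not repeat in leaves also fed LiCl or ATP. Across genes they correlated at r = -0.089 with PAP + LiCl against LiCl and at r = -0.356 with PAP + ATP against ATP. Neither pair of comparisons shares a library, and genes are not independent replicates. PAP + LiCl against LiCl called 0 of 17609 genes by limma (130 at an unadjusted p under 0.05) and 0 by edgeR and DESeq2. The interaction of PAP with LiCl called 0 of 17505 by limma (318), 0 by edgeR and 4 by DESeq2. In PAP + LiCl against LiCl, however, the salicylic acid list lay higher by camera (adjusted p = 4.5e-08, and 0.117 with an estimated correlation). The same list lay lower with PAP against control. Downstream neighbours lay higher by 0.10 (permutation p = 0.0001), but by 0.02 (permutation p = 0.305) without library 14. Camera with an estimated correlation gave p = 0.0915 for them. A PAP dose too low to act was not tested.

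Downstream neighbours lay above isolated genes in 7 comparisons by label exchange, and in none by camera with an estimated correlation (p from 0.0915 to 0.741). Against closely spaced genes with no more highly expressed upstream gene the exchange still gave permutation p under 0.05 in 7 of 7, so isolated genes that differ from closely spaced genes in general are not the whole cause, but the difference shrank from 0.30 to 0.20 for PAP + LiCl, 0.18 to 0.10 for PAP + ATP, 0.17 to 0.10 for PAP + ATP + LiCl and 0.07 to 0.03 for PAP. Reads past the end of a neighbour counted without regard to strand would raise convergent genes alike, yet downstream genes exceeded them in 7 of 7, and without libraries 4 and 20, the 2 libraries with high ribosomal RNA and plastid reads, the difference stayed past 0.05 in 2 of 2 comparisons. Transcription running on from the upstream gene, the biological explanation the series title gives, predicts a larger change where the upstream gene is expressed more strongly, and this was seen at permutation p under 0.05 in 6 of 7 comparisons with weak correlations across genes (rho 0.05 to 0.10; 0.02 for PAP, p = 0.217), and a larger change nearer to that gene, which was seen with PAP alone (rho with distance -0.06, permutation p = 0.0011) and in none of the other 6 (-0.03 to 0.03, p from 0.0906 to 0.331). It stays open as a hypothesis only: since the libraries do not keep the strand, the flat convergent list goes against reads from running on as well, ATP without PAP gave the difference too, and 6 of the comparisons share their controls.

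Within every group the libraries spread along 1 shared axis, which held 42.6% of the variance within groups against 13.6% for the next. At one end LTP3, ORE1, SAG13 and AAP2 were high, and at the other CWLP, TGG2 and BAM5; 10 of 10 extracellular ATP and early damage genes (permutation p by random lists of genes = 2e-04, the smallest possible) and 18 of 19 jasmonate genes (p = 0.0034) lay to the first end and 23 of 23 photosynthesis genes (p = 2e-04), 6 of 6 guard cell markers (p = 0.001) and 4 of 4 epidermis markers (p = 0.0124) to the other. Random lists take genes as independent, so the p values of lists along the axis may be too small where members vary together. The depth of the libraries showed little relation to the axis (rho 0.087 over 21 libraries, permutation p = 0.709). Leaves of different age may contribute, since senescence genes lay to the first end (8 of 12, permutation p = 0.0174, adjusted 0.0348). That list did not stand out, as 4 more lay there with smaller permutation p. These were high light (0.0038), heat shock (0.004), SAL1-PAP-XRN and PAPS (0.0058) and mitochondrial dysfunction genes (0.0124). Loss of RNA integrity could contribute too, since loadings rose with gene length (rho 0.352 across 17325 genes, which are not independent). In each group but PAP + LiCl the lowest-numbered library lay to the first end (PAP library 7 barely, at -1.9). In each group but PAP the highest-numbered lay to the other. Whether column order follows a replicate block is not known, and no block was tested. The samples' records give no leaf position or RNA quality, and position, wounding and the mix of cell types stay open.

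Other splits of the same libraries were counted for each result. For any difference among the 7 groups, 1 of 100 splits, the real one, gave as many as 6192 genes and the highest other gave 713, so a chance division is excluded there. For comparisons of 3 with 3 libraries there are 10 splits, too few for a share under 0.05. The real count and the highest other were 0 and 1623 for PAP, 1283 and 0 for ATP, 3102 and 1 for LiCl, 383 and 101 for PAP + ATP, 2762 and 1 for PAP + LiCl, and 3476 and 0 for PAP + ATP + LiCl, each against control. They were 0 and 0 for PAP + LiCl against LiCl and for PAP + ATP against ATP, 888 and 0 for PAP against ATP, 20 and 1 for PAP + ATP + LiCl against PAP + LiCl and 1667 and 0 against PAP + ATP. For PAP + ATP against PAP they were 1212 and 36, and for PAP + LiCl against PAP 3811 and 0. For the interactions of PAP with LiCl and with ATP, 100 of 100 splits gave 0 genes or more, and the highest gave 3007 and 2863. The high split of PAP, the first trade above, points to a structure of these 6 libraries other than their groups; the splits of the interactions mix treated and untreated libraries, so their counts can hold the effects of LiCl or ATP themselves.

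AT1G80000 (chromosome 1, 30092807 to 30097323) had 1 read in library 15 and 2 in library 19 against 288 to 580 in the other libraries of those groups, and its neighbour FRS8 (AT1G80010) had values only in control, ATP and LiCl. AT1G04800 had 5, 12 and 714 reads in the control libraries, 131, 49 and 2066 with ATP and 143, 1046 and 1 with PAP. Nuclear ribosomal RNA genes took 0.996% of reads in library 4 and 0.327% in library 20, and at most 0.0444% in the other 19. These 3 points were chosen after their values were seen and no explanation was tested.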
